A study of Mus musculus with 10 samples.

How the data were processed

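Spleen T cells and cDC2s of Cd47f/f and Cd47ΔT mice were profiled by RNA sequencing. Libraries were grouped by the cell type and genotype in the labels. Per the labels' protocols, T cell RNA was extracted with an RNeasy mini kit and made into libraries with a TruSeq stranded mRNA kit, and cDC2 RNA with an RNeasy micro kit and a SMART-seq stranded kit. Cell type and kit can therefore not be told apart in levels, and each genotype comparison stays within 1 kit. How the cells were isolated, which Cre line was used and which exons were deleted are not given in the sources used here. The deposited table gives TPM from the authors for 45706 Ensembl genes in 10 libraries, each summing to 1000000. Reads were handled with STAR, RSEM and DESeq2 (versions not given) and the GRCm38 build, per the submitters' processing notes. Counts were not used here and TPM keep no depth, so the precision that depth gives to each value is unknown, and no interval for counting error is given. Of the identifiers, 45143 (98.8%) matched the GENCODE M21 annotation of GRCm38, which gave gene symbols, classes and positions, and 563 did not. The release behind the deposited table is not given in the sources used here. The strand setting of the counting is not given either, so values of overlapping antisense genes and of near-identical copies are uncertain.

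Genes at 1 TPM or more in at least 2 T cell libraries or at least 3 cDC2 libraries were tested per cell type on log2(TPM + 1) with limma 3.58.1 (lmFit, and eBayes with a variance trend) in R 4.3.3, with genotype as the only term. p-values were adjusted by Benjamini-Hochberg and called under 0.05. The difference between the genotype effects was tested as an interaction in 1 fit of all libraries over the genes that passed both filters. Gene lists (25) and cell type marker lists (15) with at least 5 tested members were tested with limma's camera, two-sided, at a preset correlation of 0.01 and again with an estimated one, and adjusted over the gene lists or the marker lists. With an estimated correlation camera uses the residual degrees of freedom, 2 in T cells and 4 in cDC2s, so it has little power. The tests of genotype effects, the lists, the naming rule and all alternatives but protein-coding scaling were fixed before the data were examined. Named genes were, first, a fixed set per cell type. They were, second, up to 12 higher and 12 lower genes with the largest log2 fold change among those past the threshold, without overlap between genotypes and with a mean of at least 5 TPM in the higher genotype. A direction with fewer than 6 was to be filled to 6 by the smallest unadjusted p. They were, last, up to 4 members with the smallest p of each list past the test, of which up to 3 are given, or up to 2 of another list described. Unnamed gene models, antigen receptor segments, pseudogenes and mitochondrial genes were left out of the largest changes. A few genes that the rule or a count names are not reported here. Alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5 TPM, and quantile and median-of-ratios scaling. Others were no or a robust variance trend, 1 fit of all libraries, the replicate number as a block, an estimated correlation and leaving out each library. Added after the data were seen was scaling to protein-coding genes that are neither mitochondrial nor immunoglobulin. With 1 library left in a T cell group, that library is assumed to vary like the other group. With the replicate number as a block, the 4 T cell libraries leave almost no spread within a gene. Those p-values therefore rest mainly on spread pooled over genes.

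The steps were tested on simulated data with 200 changed genes. In T cells, 66.5% of genes changed by 1 on the log2 scale and 99.4% changed by 2 were recovered over 20 draws of 12453 genes, and 10.4% of calls were unchanged genes. In cDC2s these values were 52.6%, 91.1% and 5.84% over 12058 genes. For the difference between cell types, in 1 draw of 10650 genes, they were 32.0%, 83.0% and 9.45%. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.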

Results

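RNA sequencing was carried out on T cells and on type 2 conventional dendritic cells (cDC2s, antigen-presenting cells that carry the CD47 receptor SIRP alpha) from mouse spleen. Cells came from Cd47f/f mice, whose Cd47 alleles are floxed, and from Cd47ΔT mice, in which, by the genotype's name, Cd47 is deleted in T cells. CD47 is a surface protein that restrains uptake of a cell by phagocytes. There were 4 T cell libraries, 2 per genotype, and 6 cDC2 libraries, 3 per genotype. The values are TPM, transcript abundances scaled to the same total in every library. They keep no record of sequencing depth, so the depth behind each value is unknown. Between 11514 and 12594 genes reached 1 TPM in a T cell library, and between 11852 and 12146 in a cDC2 library. Across the genes tested, log2 values of T cell libraries correlated at Pearson r = 0.981 and 0.982 within a genotype and at 0.947 to 0.953 between genotypes. In cDC2s r was 0.937 to 0.966 within a genotype and 0.929 to 0.960 between genotypes. These r run across genes, which are not independent replicates. Cd47f/f library 3 stood apart among the cDC2 libraries, with r from 0.929 to 0.937 to the others, against 0.945 or more for every other pair, and with the fewest genes above 0 TPM (14172, against 14578 to 15386). Small non-coding RNAs took 16.1% to 21.3% of the TPM in control and 21.8% to 25.2% in Cd47ΔT cDC2 libraries. They took 0.124% and 0.160% in control and 0.245% and 0.456% in Cd47ΔT T cell libraries, which were made with another kit. The genotypes did not overlap in either cell type, where chance gives 10% for 3 against 3. The labels do not say whether replicates came from separate mice, so p-values measure only the spread between these libraries, which may be technical. Group values below are mean TPM ± SD with n = 2 per genotype in T cells and n = 3 in cDC2s. Each log2 fold change is Cd47ΔT over Cd47f/f on the log2(TPM + 1) scale, which understates changes of low genes, and is given ± SE with limma's Benjamini-Hochberg adjusted p.

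The targeted gene was read first. Cd47 (ENSMUSG00000055447, chromosome 16, 49800533 to 49915010, plus strand, GRCm38) stood at 138 and 233 TPM in the control T cell libraries and at 40.4 and 51.7 TPM in the Cd47ΔT T cell libraries. It fell from 185 ± 67.1 to 46.0 ± 7.99 TPM (log2 fold change -1.95 ± 0.26, adjusted p = 0.0112) in T cells. With no filter on low values, limma's adjusted p for the same change was 0.0872 (1.93e-35 to 0.0872 over all alternatives). These alternatives include the replicate block, whose T cell p-values rest mainly on spread pooled over genes. The deleted exons are not given in the sources used here, so the remaining signal can include reads from undeleted exons. These values also cannot show whether every cell in the preparations lost the gene. In cDC2s Cd47 read 149 ± 11.5 TPM in controls and 148 ± 12.1 TPM in Cd47ΔT mice (log2 fold change -0.00220 ± 0.10, adjusted p = 0.995, its sign turning with the scaling). The genotype effect on Cd47 differed between the cell types by -1.94 on the log2 scale (adjusted p = 0.00175 by limma's interaction test).

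**Figure D1:**
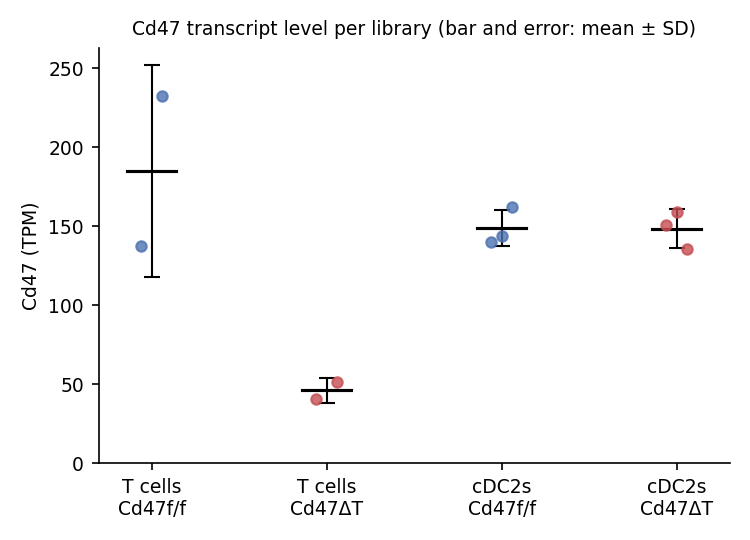
Cd47 in TPM per library (points) with mean (bar) and SD (error) for T cells and cDC2s of Cd47f/f (blue) and Cd47ΔT (red) mice. Both Cd47ΔT T cell libraries (40.4 and 51.7 TPM) lie below both control T cell libraries (138 and 233 TPM), and the cDC2 groups overlap.

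The first comparison asked how splenic T cells of Cd47ΔT mice differ from control T cells. The study's title places it in peripheral T cell survival and necroptosis. By camera, lists of effector, regulatory, checkpoint and cell cycle genes were higher in T cells of Cd47ΔT mice, and the list of naive T cell genes was lower. None of these 5 lists passed with an estimated correlation (adjusted p = 0.515 each). That test rests on 2 residual degrees of freedom in T cells, so it can hardly pass any list and not passing decides little. Its lowest unadjusted p by camera was 0.0514, for the naive list. The preset correlation in turn takes list members as nearly independent. Marker lists of 10 other cell types were higher in the same libraries, also by camera and not with an estimated correlation (adjusted p = 0.319 each). The small non-coding RNA share was also higher in both Cd47ΔT T cell libraries. Klrg1, an inhibitory receptor of effector lymphocytes, rose from 8.09 ± 0.0354 to 83.3 ± 10.6 TPM (log2 fold change 3.21 ± 0.16, adjusted p = 0.00111). Ly6c1, which encodes a GPI-anchored surface antigen, fell from 93.5 ± 14.4 to 6.45 ± 0.113 TPM (log2 fold change -3.66 ± 0.17, adjusted p = 0.00111). Cd40lg, the ligand with which helper T cells engage CD40, fell from 39.9 ± 2.91 to 11.8 ± 2.55 TPM (log2 fold change -1.69 ± 0.20, adjusted p = 0.00790). The largest named increases also included the opioid precursor Penk (3.82 ± 0.26 on the log2 scale), the decoy interleukin 1 receptor Il1r2 (3.44 ± 0.24), the chemokine receptor Ccr8 (3.32 ± 0.22) and the NK cell receptor Ncr1 (3.48 ± 0.45). The remaining ones were genes of myeloid and antigen-presenting cells, namely H2-Ab1, Cd74, H2-Aa, S100a9, C1qb, Tyrobp and H2-Eb1, with log2 fold changes from 3.14 (H2-Eb1) to 3.41 (H2-Ab1). Other large decreases were those of the sialyltransferase gene St8sia6 (-2.64 ± 0.27), Pdlim4 (-2.58 ± 0.25), Igsf23 (-2.33 ± 0.21), the alcohol dehydrogenase gene Adh1 (-2.31 ± 0.24) and the T cell receptor adaptor gene Trat1 (-1.47 ± 0.24). Arhgap29 (-1.52), Acvrl1 (-1.33), Myo6 (-1.29) and Trib2 (-1.23) also fell. Of 12453 genes tested with limma, 1058 were higher and 109 lower in Cd47ΔT T cells at adjusted p under 0.05, 907 and 44 of them by at least 2-fold. At an unadjusted p under 0.05 there were 2693 genes, where chance gives 623. The genotypes did not overlap in 48.9% of the genes, where chance gives 33.3%.

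Genes of naive and recirculating T cells were lower as a group. Of those tested, 6 of 15 were lower and none higher (11 lower when adjusted over the list alone), with a median log2 fold change of -0.54 (adjusted p = 1.44e-12 by camera, and adjusted p = 0.515 with an estimated correlation). Tcf7, a transcription factor of naive and memory T cells, fell from 1007 ± 45.5 to 631 ± 20.6 TPM (log2 fold change -0.67 ± 0.0921, adjusted p = 0.0118). Il7r, the receptor for the survival cytokine interleukin 7, fell from 277 ± 32.7 to 168 ± 5.06 TPM (log2 fold change -0.71 ± 0.12, adjusted p = 0.0199), and the actin cross-linker gene Actn1 from 209 to 114 TPM (log2 -0.87 ± 0.15). The lymph node homing receptor Ccr7 fell from 416 to 286 TPM (log2 -0.54 ± 0.10). Effector and memory genes were higher as a group. Of those tested, 19 of 30 were higher and none lower (26 higher when adjusted over the list alone), with a median of 1.30 (adjusted p = 8.51e-17 by camera, and adjusted p = 0.515 with an estimated correlation). Beside Klrg1, the galectin gene Lgals1 rose from 208 to 731 TPM (log2 1.81 ± 0.10), and the calcium-binding protein gene S100a4 from 129 to 553 TPM (log2 2.09 ± 0.16). The adhesion receptor Cd44 rose from 25.1 ± 6.73 to 57.9 ± 0.856 TPM (log2 fold change 1.20 ± 0.20, adjusted p = 0.0191). Regulatory T cell genes rose in 8 of 14 (11 when adjusted over the list alone), with a median of 1.30 (adjusted p = 1.41e-07 by camera, and adjusted p = 0.515 with an estimated correlation). They included the costimulatory receptor Tnfrsf9 from 18.3 to 62.4 TPM (log2 1.71 ± 0.15), Capg from 43.2 to 128 TPM (log2 1.54 ± 0.14) and the inhibitory receptor Tigit from 12.8 to 82.3 TPM (log2 2.58 ± 0.23). Follicular helper and checkpoint genes rose in 8 of 16 (9 when adjusted over the list alone), with a median of 1.32 (adjusted p = 8.11e-06 by camera, and adjusted p = 0.515 with an estimated correlation). Among them were the ectonucleotidase gene Entpd1 from 2.37 to 13.5 TPM (log2 2.11 ± 0.20) and the inhibitory receptor Pdcd1 from 7.11 to 43.6 TPM (log2 2.41 ± 0.27). Cell cycle genes rose in 29 of 32, and in all 32 when adjusted over the list alone, with a median of 1.76 (adjusted p = 9.80e-23 by camera, and adjusted p = 0.515 with an estimated correlation). The mitotic kinase gene Cdk1 rose from 13.6 ± 0.0849 to 61.2 ± 1.15 TPM (log2 fold change 2.09 ± 0.14, adjusted p = 0.00217). Also higher were the mitotic survivin gene Birc5 from 15.8 to 68.6 TPM (log2 2.06 ± 0.19) and the thymidine kinase gene Tk1 from 10.5 to 38.8 TPM (log2 1.80 ± 0.17). The T cell receptor list did not pass as a whole (adjusted p = 0.112 by camera; 2 higher and 1 lower when adjusted over the list alone). Its median was 0.0171, against a mean of -0.0581, and turned negative under each other scaling. The list passed as lower under median-of-ratios scaling (adjusted p = 0.0355) and in 1 fit of all libraries (0.0420). The same held without control library 2 (0.0458) and without Cd47ΔT library 1 (0.0191; 0.0191 to 0.653 over all alternatives). Within it, the coreceptor genes Cd8a and Cd8b1 rose from 356 to 506 TPM (log2 0.51 ± 0.11) and from 844 to 1189 TPM (log2 0.49 ± 0.0918). Cd4 fell from 179.9 ± 13.9 to 84.1 ± 33.8 TPM (log2 fold change -1.15 ± 0.26, adjusted p = 0.0481). By limma, the Cd4 call ended with a pseudocount of 0.1 (adjusted p = 0.0581), with no filter (0.169), with a filter of 5 TPM (0.0518), under quantile scaling (0.0571), under median-of-ratios scaling (0.0517), without the variance trend (0.0905) and with a robust trend (0.0512). It also did so without control library 1 (0.120), without control library 2 (0.115) and without Cd47ΔT library 2 (0.0873; 8.11e-14 to 0.169 over all alternatives). That of Cd8a ended with no filter (adjusted p = 0.111), under quantile scaling (0.0622), under median-of-ratios scaling (0.101), without the variance trend (0.138) and in 1 fit of all libraries (0.489). The same held without Cd47ΔT library 1 (0.223) and without Cd47ΔT library 2 (0.282; 0.000212 to 0.489 over all alternatives). The Cd8b1 call did so with no filter (adjusted p = 0.0974), under median-of-ratios scaling (0.190), without the variance trend (0.130) and in 1 fit of all libraries (0.356). It also did so without Cd47ΔT library 1 (0.180) and without Cd47ΔT library 2 (0.251; 5.61e-05 to 0.356 over all alternatives). With an estimated correlation between genes no list passed in T cells.

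Genes of necroptosis and TNF receptor death signalling did not pass as a group. Of those tested, 1 of 19 was higher, also when adjusted over the list alone, with a median log2 fold change of 0.10 that turned negative under median-of-ratios and quantile scaling (adjusted p = 0.662 by camera). That gene was Mlkl, the executor of necroptosis, which rose from a low level, from 0.505 ± 0.0778 to 2.80 ± 0.177 TPM (log2 fold change 1.33 ± 0.22, adjusted p = 0.0185). By limma the call ended with no filter (adjusted p = 0.0779), under quantile scaling (0.0721) and without control library 1 (0.0639; 1.78e-05 to 0.0779 over all alternatives). Ripk3, the kinase that phosphorylates MLKL, read 29.8 ± 1.94 and 41.9 ± 1.27 TPM (log2 fold change 0.48 ± 0.14, adjusted p = 0.0976). Its adjusted p by limma ran from 0.0432 to 0.730 over all alternatives and was under 0.05 in 2 of them, 0.0432 without control library 2 being one. Log2 fold changes were 0.0508 ± 0.19 for Ripk1, 0.0314 ± 0.11 for Casp8, -0.10 ± 0.15 for Fas and -0.0162 ± 0.16 for Tnfrsf1a, with adjusted p from 0.825 (Fas) to 0.976 (Tnfrsf1a). The signs of Ripk1 and Casp8 turned under quantile and median-of-ratios scaling. BCL2 family and caspase genes rose as a group, 4 of 21 over all genes and 9 when adjusted over the list alone, with a median of 0.37 (adjusted p = 0.00725 by camera, and adjusted p = 0.653 with an estimated correlation). With the replicate number as a block this list did not pass. The anti-apoptotic members Bcl2l1, Bcl2a1b and Bcl2a1d rose from 13.5 to 28.5 TPM (log2 1.03 ± 0.18), from 30.8 to 67.0 TPM (log2 1.09 ± 0.15) and from 8.28 to 26.2 TPM (log2 1.52 ± 0.28), the split between the near-identical Bcl2a1 copies being uncertain. Bcl2 read 53.7 ± 12.2 and 79.9 ± 4.71 TPM and did not pass (adjusted p = 0.112). Over all alternatives its adjusted p by limma ran from 0.00253 to 0.521 and was under 0.05 in 2, at 0.0214 without control library 2. Type I interferon response genes rose in 9 of 30 (19 when adjusted over the list alone), with a median of 0.56 (adjusted p = 1.30e-05 by camera, and adjusted p = 0.515 with an estimated correlation). The antiviral genes Oas1a, Mx1 and Isg20 rose from 9.95 to 32.6 TPM (log2 1.61 ± 0.19), from 6.05 to 18.7 TPM (log2 1.47 ± 0.19) and from 20.2 to 38.1 TPM (log2 0.88 ± 0.14). The interferon gamma list did not pass (adjusted p = 0.308 by camera), and 2 members were higher when adjusted over the list alone. Cxcl10 rose from 1.27 to 10.1 TPM (log2 2.29 ± 0.21) and Gbp3 from 12.1 to 23.6 TPM (log2 0.90 ± 0.20). The list passed without control library 2 (adjusted p = 0.0314 by camera), and its direction turned without control library 1 (0.872; 0.0314 to 0.884 over all alternatives). Chemokine genes rose in 7 of 7, also when adjusted over the list alone, with a median of 1.40 (adjusted p = 2.08e-07 by camera, and adjusted p = 0.515 with an estimated correlation). Ccl5 rose from 347 to 750.0 TPM (log2 1.11 ± 0.11) and Ccl6 from 2.89 to 30.3 TPM (log2 2.93 ± 0.36). NF-kB targets rose in 4 of 24 (9 when adjusted over the list alone; adjusted p = 0.00205 by camera, and adjusted p = 0.515 with an estimated correlation). Among them were the activation marker Cd83 from 5.05 to 32.5 TPM (log2 2.47 ± 0.17), the chemokine gene Ccl3 from 2.04 to 7.0 TPM (log2 1.40 ± 0.21) and Tnfaip2 from 0.915 to 3.35 TPM (log2 1.19 ± 0.22). Cytokine genes rose in 4 of 15 (6 higher and 1 lower when adjusted over the list alone; adjusted p = 0.0241 by camera, and adjusted p = 0.606 with an estimated correlation). They were the regulatory cytokine Il10 from 0.740 to 7.72 TPM (log2 2.32 ± 0.22), Csf1 from 0.980 to 5.43 TPM (log2 1.70 ± 0.24), Il18 from 0.670 to 4.67 TPM (log2 1.80 ± 0.33) and, named after its value was seen, Tnfsf14 (0.93 ± 0.20). That list call ended with a filter of 5 TPM (adjusted p = 0.148) and in 1 fit of all libraries (0.0682). The same held without control library 2 (0.253) and without Cd47ΔT library 1 (0.0627; 0.000257 to 0.606 over all alternatives).

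Nuclear genes of oxidative phosphorylation rose in 7 of 76 (17 when adjusted over the list alone), with a median of 0.30 (adjusted p = 6.43e-07 by camera, and adjusted p = 0.633 with an estimated correlation). Cox5b, Cox7b and Ndufa4, subunits of the respiratory chain, rose from 181 to 287 TPM (log2 0.66 ± 0.11), from 124 to 191 TPM (log2 0.62 ± 0.11) and from 329.9 to 478 TPM (log2 0.53 ± 0.10). By limma, the calls of these 3 genes ended under median-of-ratios scaling (adjusted p = 0.121, 0.119 and 0.208), without the variance trend (0.0711, 0.0755 and 0.109) and with no filter (0.0872, 0.0854 and 0.0890). They also ended without Cd47ΔT library 1 (0.218, 0.288 and 0.297) or 2 (0.0583, 0.108 and 0.147). Those of Cox7b and Ndufa4 also ended under quantile scaling (0.0618 and 0.0853) and in 1 fit of all libraries (0.106 and 0.103). Over all alternatives their adjusted p ran from 6.78e-06 to 0.218 (Cox5b), 8.63e-05 to 0.288 (Cox7b) and 0.000111 to 0.297 (Ndufa4). Unfolded protein response genes rose in 3 of 16 (7 when adjusted over the list alone), with a median of 0.36 (adjusted p = 0.0292 by camera, and adjusted p = 0.653 with an estimated correlation). They were Sdf2l1 from 17.1 to 30.7 TPM (log2 0.81 ± 0.15), the asparagine synthetase gene Asns from 0.495 to 2.76 TPM (log2 1.31 ± 0.25) and Xbp1, a transcription factor of secretory cells, from 35.1 to 56.6 TPM (log2 0.68 ± 0.15). With the replicate number as a block the unfolded protein response list did not pass. The list call ended without Cd47ΔT library 1 (adjusted p = 0.154) and without Cd47ΔT library 2 (0.216; 0.00366 to 0.653 over all alternatives). Cytosolic ribosomal protein genes were lower relative to other genes, with a median of -0.11 (adjusted p = 1.94e-09 by camera, and adjusted p = 0.653 with an estimated correlation). Of those tested, 1 of 81 passed as lower, Rpl12 from 4622 to 3354 TPM (log2 -0.46 ± 0.10), 2 as higher (Rps27l and Rps12l1, named after their values were seen) and none when adjusted over the list alone. Rpl8 had a log2 fold change of -0.36 and did not pass. The list call ended under quantile scaling (adjusted p = 0.641), and its direction turned without control library 1 (0.872; 5.89e-39 to 0.872 over all alternatives). Immediate early genes passed as lower relative to other genes, with a median of -0.0353 but a mean of 0.0405 (adjusted p = 0.0439 by camera, and adjusted p = 0.653 with an estimated correlation). None of 21 passed alone, also when adjusted over the list alone, and Zfp36, Ier2 and Ppp1r15a had log2 fold changes of -0.34, -0.30 and -0.42. That list call ended under quantile scaling (adjusted p = 0.0770), under median-of-ratios scaling (0.0620), in 1 fit of all libraries (0.0941) and with the replicate number as a block. It also did so without Cd47ΔT library 1 (0.130) and without Cd47ΔT library 2 (0.162; 0.0194 to 0.653 over all alternatives). The lists of p53 targets, MHC class I presentation, glycolysis, cholesterol synthesis and heat shock proteins did not pass, with adjusted p from 0.0804 to 0.205 by camera. The cholesterol synthesis list passed as lower under median-of-ratios scaling (adjusted p = 0.0397) and without Cd47ΔT library 2 (0.0483; 0.0397 to 0.688 over all alternatives). Heat shock protein genes passed as lower without control library 1 (adjusted p = 0.000593) and turned direction without control library 2 (0.380; 0.000593 to 0.670 over all alternatives).

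Transcripts of cells other than T cells were higher in both Cd47ΔT T cell libraries, beside each of the gene groups above. A gene under 1 TPM in a control library was tested only where a Cd47ΔT library reached 1 TPM. The filter therefore favours higher members in the shares of marker lists below and of gene lists. Markers of red pulp macrophages were higher in 11 of 11 (median 2.46), of monocytes in 10 of 10 (median 2.14), of NK cells in 7 of 9 (median 2.66), of B cells in 7 of 8 (median 1.76) and of plasma cells in 7 of 8 (median 1.61). These lists had adjusted p from 2.41e-11 to 7.14e-06 by camera, and adjusted p = 0.319 each with an estimated correlation. When adjusted over the list alone, 11, 10, 8, 8 and 8 of their genes were higher. Markers of cDC1s were higher in 6 of 7 (median 1.55), of cDC2s in 6 of 9 (median 1.48), of neutrophils in 3 of 5 (median 2.15), of erythroid cells in 4 of 6 (median 1.64) and of mast cells, basophils and eosinophils in 4 of 7 (median 1.61). These lists also passed, with adjusted p from 5.74e-06 to 0.0177 by camera, and adjusted p = 0.319 each with an estimated correlation. When adjusted over the list alone, 7, 7, 5, 6 and 7 of their genes were higher, and 1 cDC2 marker, Cd4, was lower over all genes and 2 were when adjusted over the list alone. Plasmacytoid DC markers, higher in 3 of 8 (median 1.10), did not pass (adjusted p = 0.0677 by camera), nor did sex-linked genes (adjusted p = 0.979 by camera). T cell markers had a median of -0.12, with 1 of 10 lower (adjusted p = 0.00391 by camera, and adjusted p = 0.330 with an estimated correlation). Among abundant markers, singled out after their values were seen, the lysozyme gene Lyz2 read 19.4 and 46.9 TPM in controls and 194 and 349.7 TPM in Cd47ΔT libraries. The B cell receptor gene Cd79a read 0.970 and 2.03 against 10.4 and 37.8 TPM, and the plasma cell gene Jchain 57.0 and 64.3 against 309 and 345 TPM. MHC class II genes rose in 7 of 13 (11 when adjusted over the list alone), with a median of 1.25 (adjusted p = 1.04e-06 by camera, and adjusted p = 0.515 with an estimated correlation). The invariant chain gene Cd74 rose from 27.4 ± 7.30 to 286 ± 106 TPM (log2 fold change 3.31 ± 0.29, adjusted p = 0.00415). H2-Ab1 and H2-Aa rose from 6.76 to 85.8 TPM (log2 3.41 ± 0.32) and from 8.52 to 98.4 TPM (log2 3.31 ± 0.33). SIRP alpha, Fc receptor and phagocytosis genes rose in 16 of 25 (18 higher and 1 lower when adjusted over the list alone), with a median of 1.73 (adjusted p = 1.56e-08 by camera, and adjusted p = 0.574 with an estimated correlation). Sirpa, the CD47 receptor, rose from 2.35 to 21.9 TPM (log2 2.73 ± 0.32), the Fc receptor gene Fcgr4 from 0.615 to 8.37 TPM (log2 2.53 ± 0.24) and the Fc receptor signalling chain gene Fcer1g from 9.23 to 81.8 TPM (log2 3.03 ± 0.35). Dendritic cell maturation genes rose in 8 of 20, with 1 lower (11 and 1 when adjusted over the list alone; adjusted p = 0.000123 by camera, and adjusted p = 0.515 with an estimated correlation). Among these were Cd83, Ccl5 and the cytokine subunit gene Ebi3 from 2.14 to 9.45 TPM (log2 1.74 ± 0.24). Control library 1 stood apart by sex-linked transcripts. Xist, the X inactivation RNA, read 33.2 TPM there, 6.21 TPM in Cd47ΔT library 1 and at most 0.01 TPM in the remaining T cell libraries. The Y-linked gene Ddx3y read 10.9 TPM in control library 1 and 27.2 to 35.7 TPM in the others. Without control library 1, 585 genes were higher and 140 lower, without control library 2 1439 and 129, without Cd47ΔT library 1 953 and 51, and without Cd47ΔT library 2 841 and 57. Of 69 named genes past the threshold, 59, 64, 50 and 55 remained past it without control libraries 1 and 2 and Cd47ΔT libraries 1 and 2. Beside Cd4, Cd8a, Cd8b1, Mlkl, Cox5b, Cox7b and Ndufa4, the named calls that ended without control library 1 were those of Asns, Bcl2a1d, Gbp3, Il18, Rpl12, S100a9, Tnfaip2 and Xbp1, and without control library 2 Arhgap29, Asns, Tnfaip2 and Trat1. They were Actn1, Acvrl1, Arhgap29, Bcl2a1b, Bcl2a1d, Bcl2l1, Ccr7, Gbp3, Il7r, Isg20, Rpl12, Sdf2l1, Tcf7 and Xbp1 without Cd47ΔT library 1, and without Cd47ΔT library 2 Bcl2l1, Ccr7, Gbp3, Il7r, Isg20, Rpl12, Sdf2l1 and Xbp1. Those that ended under quantile scaling were Asns, Gbp3, Il18 and Tnfaip2, under median-of-ratios scaling Ccr7 and Rpl12, and with a pseudocount of 0.1 Il18. Without the variance trend they were Actn1, Ccr7, Il7r, Rpl12, Tcf7 and Xbp1, and in 1 fit of all libraries Asns, Bcl2l1, Ccr7, Gbp3, Il18, Il7r, Myo6 and Tnfaip2. Of all, 4 of the 69 named calls stayed with no filter. With no filter on low values 14 genes were higher and 1 lower. Increases made up 90.7% of the calls, 66.1% under quantile scaling (655 and 336) and 78.2% under median-of-ratios scaling (946 and 264). These scalings moved the median of all genes from 0.10 to -0.0812 and -0.0408.

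**Figure D2:**
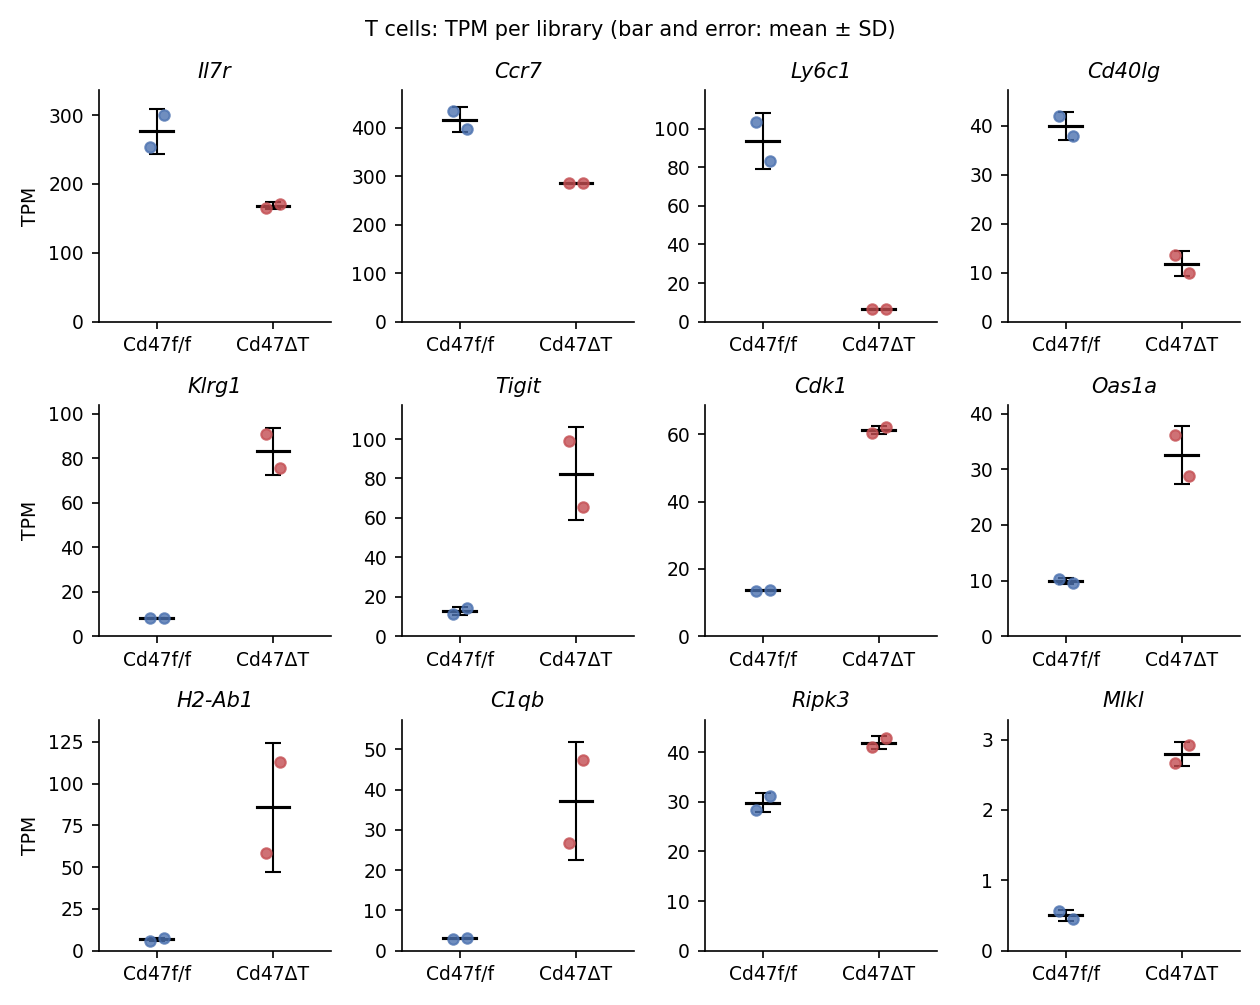
TPM per T cell library (points, n = 2 per genotype) with mean (bar) and SD (error) for 12 genes, on linear axes that start at 0; Cd47f/f is blue and Cd47ΔT red. Il7r, Ccr7, Ly6c1 and Cd40lg fell, Klrg1, Tigit, Cdk1, Oas1a, H2-Ab1, C1qb and Mlkl rose, and Ripk3 did not pass the test.

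The second comparison asked what differs in cDC2s of Cd47ΔT mice, which live beside T cells in which Cd47 was targeted. By camera, the type I interferon and immediate early lists were lower in cDC2s of Cd47ΔT mice, with 3 of 30 and none of 22 members past the threshold, and neither passed with an estimated correlation (adjusted p = 0.242 and 0.615). Single genes past the threshold included the lower surface molecule genes Itgam, Cd209a and Cd4 and the higher NF-kB subunit gene Relb. The integrin gene Itgam, which encodes CD11b, fell from 72.9 ± 6.22 to 21.5 ± 3.26 TPM (log2 fold change -1.72 ± 0.14, adjusted p = 0.0120). The C-type lectin gene Cd209a fell from 91.2 ± 10.1 to 31.0 ± 6.48 TPM (log2 fold change -1.54 ± 0.17, adjusted p = 0.0200). Dusp6, a phosphatase that limits ERK signalling, fell from 53.8 ± 11.9 to 10.6 ± 1.61 TPM (log2 fold change -2.23 ± 0.19, adjusted p = 0.0120). The collagen-binding endocytic receptor gene Mrc2 rose from 7.11 ± 2.12 to 53.4 ± 12.5 TPM (log2 fold change 2.75 ± 0.24, adjusted p = 0.0120). Aldh1a2, which makes retinoic acid, rose from 4.19 ± 0.614 to 19.5 ± 1.26 TPM (log2 fold change 1.98 ± 0.18, adjusted p = 0.0142). The other largest named increases were those of the growth factor genes Bmp2 (1.99 ± 0.20 on the log2 scale) and Mdk (1.85 ± 0.23), the carbonic anhydrase gene Car2 (1.57 ± 0.24), the calcium channel gene Ryr3 (1.32 ± 0.16), Pxdc1, Timm22, Chst7, Lad1, Igsf3 and Nab2, the last 6 between 1.43 (Nab2) and 1.89 (Pxdc1). The other largest named decreases were those of the calcium channel gene Cacna1e (-2.14 ± 0.21), Slc44a5 (-2.09 ± 0.29), the adaptor gene Bank1 (-2.05 ± 0.25), the chemokine gene Ccl3 (-1.68 ± 0.27), Cd101 (-1.53 ± 0.18) and Emb (-1.28 ± 0.18). The interferon-induced genes Ifit1bl1 (-1.56 ± 0.21), Oasl2 (-1.39 ± 0.18) and Ifi213 (-1.34 ± 0.14) belonged to the same group, the split among similar Ifit copies being uncertain. Of 12058 genes tested with limma, 30 were higher and 46 lower at adjusted p under 0.05, 23 and 28 of them by at least 2-fold. At an unadjusted p under 0.05 there were 1618 genes, where chance gives 603, and in 19.9% the genotypes did not overlap, where chance gives 10%. By limma no gene passed without control library 1, Cd47ΔT library 1 or Cd47ΔT library 3 (1322, 1277 and 1371 genes at an unadjusted p under 0.05), and 14, 12 and 4 passed without control library 2, control library 3 and Cd47ΔT library 2. Of 31 named calls, 6, 5 and 3 stayed without these 3 libraries, 2 with no filter and 8 without the variance trend. With the replicate number as a block 1 of the 31 stayed. Named calls that ended with another pseudocount were those of Ccl3 and Chst7 with a pseudocount of 0.1 and Car2, Ccl3 and Chst7 with a pseudocount of 5. They were Ccl3, Chst7 and Timm22 under quantile scaling, Ccl3 under median-of-ratios scaling, Ccl3, Gbp4 and Timm22 under protein-coding scaling and Gbp9 in 1 fit of all libraries. Higher and lower counts were 2 and 4 with no filter on low values, 7 and 5 without the variance trend, 68 and 103 in 1 fit of all libraries, 34 and 36 under quantile scaling and 40 and 35 under median-of-ratios scaling. With the replicate number as a block they were 3 and 1. The share of increases was 39.5% as deposited, 53.3% under median-of-ratios scaling and 53.03% under protein-coding scaling.

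Type I interferon response genes were lower as a group in cDC2s. Of those tested, 3 of 30 passed as lower over all genes and 22 when adjusted over the list alone, with a median log2 fold change of -0.70 (adjusted p = 2.51e-13 by camera, and adjusted p = 0.242 with an estimated correlation). The small non-coding RNA share, 16.1% to 21.3% in controls and 21.8% to 25.2% in Cd47ΔT mice, moved with genotype alongside this and the other cDC2 gene groups. The antiviral gene Oasl2 fell from 67.6 to 25.3 TPM (log2 -1.39 ± 0.18), and the interferon-induced gene Ifit3 from 94.2 ± 2.19 to 40.8 ± 8.68 TPM (log2 fold change -1.21 ± 0.16, adjusted p = 0.0266). Irf7, a transcription factor that amplifies the interferon response, fell from 111 ± 10.3 to 54.2 ± 8.83 TPM (log2 fold change -1.03 ± 0.14, adjusted p = 0.0293). Interferon gamma response genes passed as lower, 2 of 20 over all genes and 4 lower with 1 higher when adjusted over the list alone, with a median of -0.18 (adjusted p = 0.0442 by camera, and adjusted p = 0.615 with an estimated correlation). The guanylate-binding protein genes Gbp9 and Gbp4, of a family of similar copies, fell from 75.1 to 43.8 TPM (log2 -0.77 ± 0.10) and from 45.2 to 20.6 TPM (log2 -1.11 ± 0.15), and Irgm1 had -0.62 ± 0.14 and did not pass. That list call ended with a filter of 5 TPM (adjusted p = 0.0754), under median-of-ratios scaling (0.0673), under protein-coding scaling (0.0688), in 1 fit of all libraries (0.1004) and with the replicate number as a block. The same held without control library 1 (0.0670), without control library 2 (0.0772), without control library 3 (0.0908) and without Cd47ΔT library 1 (0.163; 0.0104 to 0.615 over all alternatives). Immediate early genes, the first to respond to stimulation, were lower as a group, with a median of -0.74 (adjusted p = 1.87e-06 by camera, and adjusted p = 0.615 with an estimated correlation). None of 22 passed over all genes and 10 when adjusted over the list alone. Egr1 read 376 ± 191 TPM in controls and 127 ± 42.4 TPM in Cd47ΔT mice, Jun 650.5 ± 242 and 315 ± 42.2, and Jund 186 ± 46.6 and 112 ± 11.4. MHC class II genes were lower as a group, none of 13 over all genes and 4 when adjusted over the list alone, with a median of -0.21 (adjusted p = 0.00955 by camera, and adjusted p = 0.615 with an estimated correlation). H2-Ob, H2-Oa and H2-DMa, which act in peptide loading, had log2 fold changes of -0.49, -0.35 and -0.42. Ribosomal protein genes were lower as a group with none of 80 past the threshold, also when adjusted over the list alone, and a median of -0.12 (adjusted p = 0.000345 by camera, and adjusted p = 0.660 with an estimated correlation). Rpl22l1, Rps23 and Rpl32 had -0.57, -0.26 and -0.24. The MHC class II call ended under median-of-ratios scaling (adjusted p = 0.0563), in 1 fit of all libraries (0.144) and without control library 3 (0.0893; 0.00149 to 0.615 over all alternatives). The ribosomal call ended under median-of-ratios scaling (adjusted p = 0.0563) and without control library 3 (0.151; 5.47e-06 to 0.660 over all alternatives). Dendritic cell maturation genes were higher as a group, 2 of 23 over all genes and 5 higher with 1 lower when adjusted over the list alone, with a median of 0.30 (adjusted p = 0.000345 by camera, and adjusted p = 0.242 with an estimated correlation). The adaptor gene Samsn1 rose from 90.2 ± 3.63 to 144 ± 9.0 TPM (log2 fold change 0.66 ± 0.0934, adjusted p = 0.0294). Relb rose from 272 ± 13.6 to 415 ± 30.3 TPM (log2 fold change 0.61 ± 0.0905, adjusted p = 0.0364), while Marcksl1 had 0.64 ± 0.12 and did not pass. Cell cycle genes were higher as a group with none of 32 past the threshold, also when adjusted over the list alone, and a median of 0.21 (adjusted p = 1.26e-08 by camera, and adjusted p = 0.242 with an estimated correlation). Ccnb1 had 0.67, Rrm2 0.43 and Kif11 0.36. Oxidative phosphorylation genes were higher as a group with none of 73 past the threshold, also when adjusted over the list alone, and a median of 0.0664 (adjusted p = 0.0130 by camera, and adjusted p = 0.615 with an estimated correlation). Atp5h had 0.41, Ndufb6 0.52 and Ndufa12 0.47. That call ended without control library 1 (adjusted p = 0.0893) and without Cd47ΔT library 3 (0.221; 0.000996 to 0.615 over all alternatives). The regulatory T cell list, of which cDC2s expressed 6 genes, passed as higher with none past the threshold alone and 2 when adjusted over the list alone, at a median of 0.60 (adjusted p = 0.0388 by camera, and adjusted p = 0.391 with an estimated correlation). Icos, Tnfrsf9 and Capg, which are not restricted to regulatory T cells, had 0.91, 1.30 and 0.69. This call ended with no filter (adjusted p = 0.337), with a filter of 5 TPM (0.0754), under quantile scaling (0.0702), under median-of-ratios scaling (0.0673) and under protein-coding scaling (0.0688). It also did so without control library 1 (0.0893), without control library 3 (0.05002), without Cd47ΔT library 1 (0.0984) and without Cd47ΔT library 3 (0.0931; 0.0180 to 0.391 over all alternatives). With an estimated correlation between genes no list passed in cDC2s.

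The fixed genes Sirpa, Cd86, Cd80, Cd40 and Ccr7 did not pass the test. Sirpa, which encodes SIRP alpha, read 459 ± 30.2 TPM in controls and 352 ± 51.8 TPM in Cd47ΔT mice (log2 fold change -0.39 ± 0.12, adjusted p = 0.222). The costimulatory genes Cd86 and Cd80 read 57.2 ± 7.16 and 81.2 ± 17.5 TPM (adjusted p = 0.268) and 23.6 ± 5.15 and 24.9 ± 5.44 TPM (adjusted p = 0.921). The CD40 gene Cd40 read 47.5 ± 9.51 and 38.1 ± 5.14 TPM (adjusted p = 0.512) and the migration receptor gene Ccr7 48.4 ± 10.5 and 66.1 ± 10.9 TPM (adjusted p = 0.331). Of the ligands that can trigger cell death, Tnf read 31.3 ± 9.47 and 20.9 ± 3.73 TPM (adjusted p = 0.367), Fasl 3.97 ± 2.37 and 4.57 ± 3.14 TPM (adjusted p = 0.939) and Tnfsf10, which encodes TRAIL, 2.78 ± 1.75 and 1.72 ± 1.31 TPM (adjusted p = 0.745). The inflammatory cytokine gene Il1b read 488 ± 331 and 159 ± 53.8 TPM (-1.47 ± 0.42 on the log2 scale, adjusted p = 0.190), and Il6 was below the filter. Il12b, the efferocytosis receptor gene Mertk and the integrin gene Itgax had log2 fold changes of -0.21 ± 0.33, 0.0471 ± 0.34 and -0.21 ± 0.0857. The list of necroptosis and TNF receptor death signalling did not pass (adjusted p = 0.765 by camera), with none of 20 past the threshold, also when adjusted over the list alone. Its median of -0.0304 turned positive under each other scaling, and the nucleic acid sensor gene Zbp1 and Tnfrsf1a had -0.94 ± 0.22 and -0.55 ± 0.16. SIRP alpha, Fc receptor and phagocytosis genes did not pass as a list (adjusted p = 0.0697 by camera), with Itgam lower over all genes and 7 lower and 3 higher when adjusted over the list alone. Fcgr4 had -1.02 ± 0.18. The list passed as lower with no filter on low values (adjusted p = 0.0187), with a filter of 5 TPM (0.00840), under quantile scaling (0.0456) and without control library 2 (0.0341; 0.00840 to 0.615 over all alternatives). Cytokine genes did not pass as a list (adjusted p = 0.198 by camera), 3 lower and 1 higher when adjusted over the list alone, with Tnfsf14 at -1.99 ± 0.35 and Ltb at 0.37 ± 0.0906. NF-kB targets had a median of 0.0397 and a mean of -0.10 (adjusted p = 0.282 by camera), with Relb higher and Ccl3 lower, and 2 higher and 3 lower when adjusted over the list alone. The naive T cell list had a median of -0.13 and a mean of 0.0440 (adjusted p = 0.436 by camera), with 2 higher and 2 lower when adjusted over the list alone. Tcf7, which cDC2s also expressed, rose from 63.8 ± 4.86 to 146 ± 28.9 TPM (log2 fold change 1.16 ± 0.15, adjusted p = 0.0250), and the chromatin organiser gene Satb1 had -0.50 ± 0.0925. Lists of apoptosis, p53 targets, effector T cells, follicular helper and checkpoint genes, the T cell receptor, MHC class I, chemokines, glycolysis, cholesterol synthesis, the unfolded protein response and heat shock did not pass, with adjusted p from 0.0659 to 0.949 by camera. The p53 list passed as higher without Cd47ΔT library 2 (adjusted p = 0.0488; 0.0488 to 0.392 over all alternatives). Of 14 markers of cDC2s, 3 were lower, Itgam, Cd209a and Cd4 (166 ± 19.0 to 85.1 ± 6.83 TPM, adjusted p = 0.0203), 4 when adjusted over the list alone. The list passed as lower (adjusted p = 0.00596 by camera, and adjusted p = 0.226 with an estimated correlation). Monocyte markers were lower as a group (1 of 9 lower, 2 when adjusted over the list alone; adjusted p = 0.0155 by camera, and adjusted p = 0.226 with an estimated correlation). Plasmacytoid DC markers (none of 5 over all genes, 2 when adjusted over the list alone; adjusted p = 0.00596 by camera, and adjusted p = 0.221 with an estimated correlation) were higher as a group. So were erythroid markers (1 of 5, Car2, also when adjusted over the list alone; adjusted p = 0.0117 by camera, and adjusted p = 0.226 with an estimated correlation). Markers of B cells, cDC1s and red pulp macrophages did not pass, with adjusted p from 0.0844 to 0.282 by camera.

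**Figure D3:**
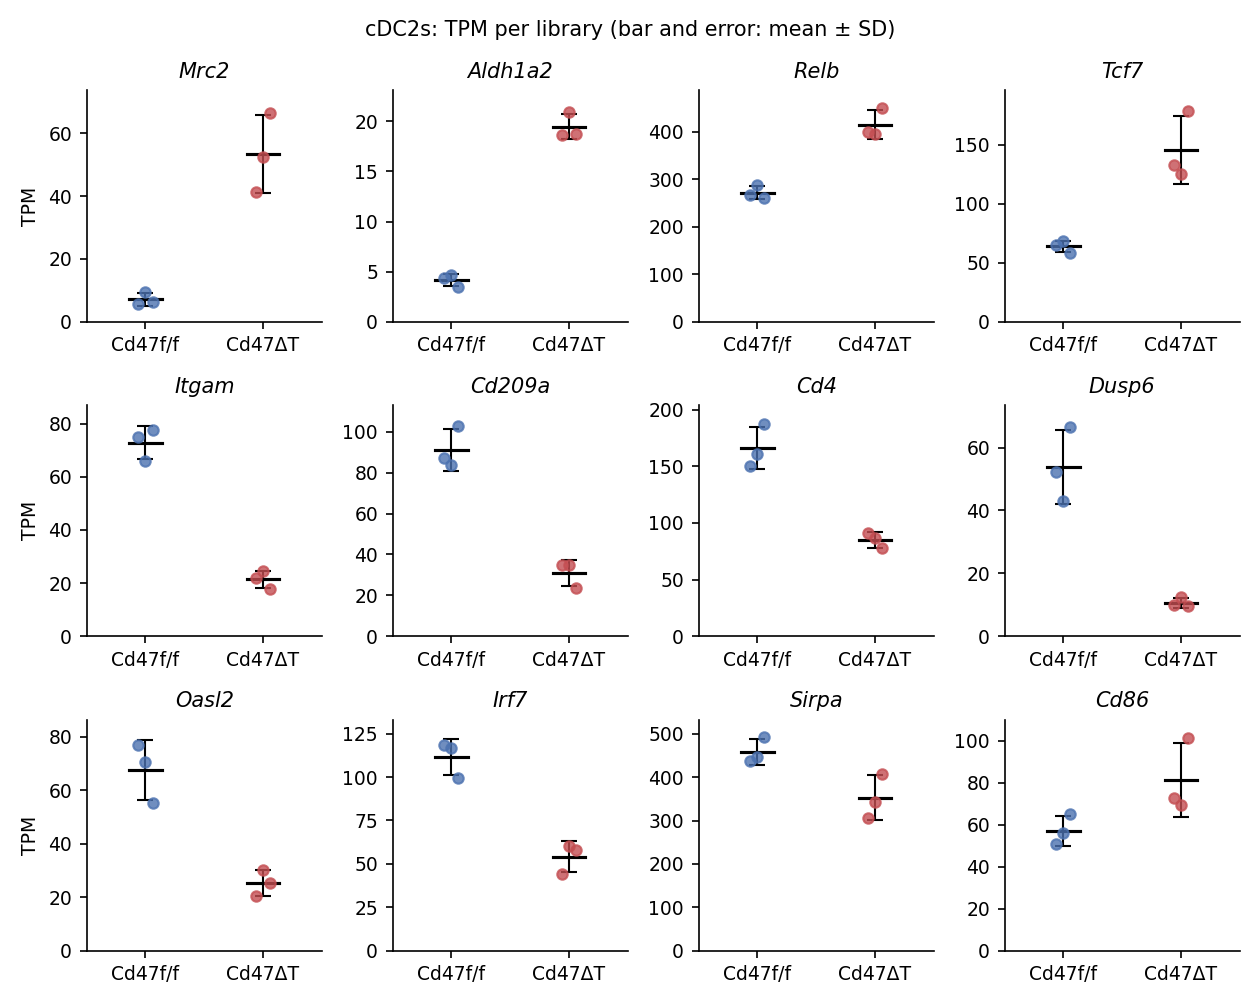
TPM per cDC2 library (points, n = 3 per genotype) with mean (bar) and SD (error) for 12 genes, on linear axes that start at 0; Cd47f/f is blue and Cd47ΔT red. Mrc2, Aldh1a2, Relb and Tcf7 rose, Itgam, Cd209a, Cd4, Dusp6, Oasl2 and Irf7 fell, and Sirpa and Cd86 did not pass the test.

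**Figure D4:**
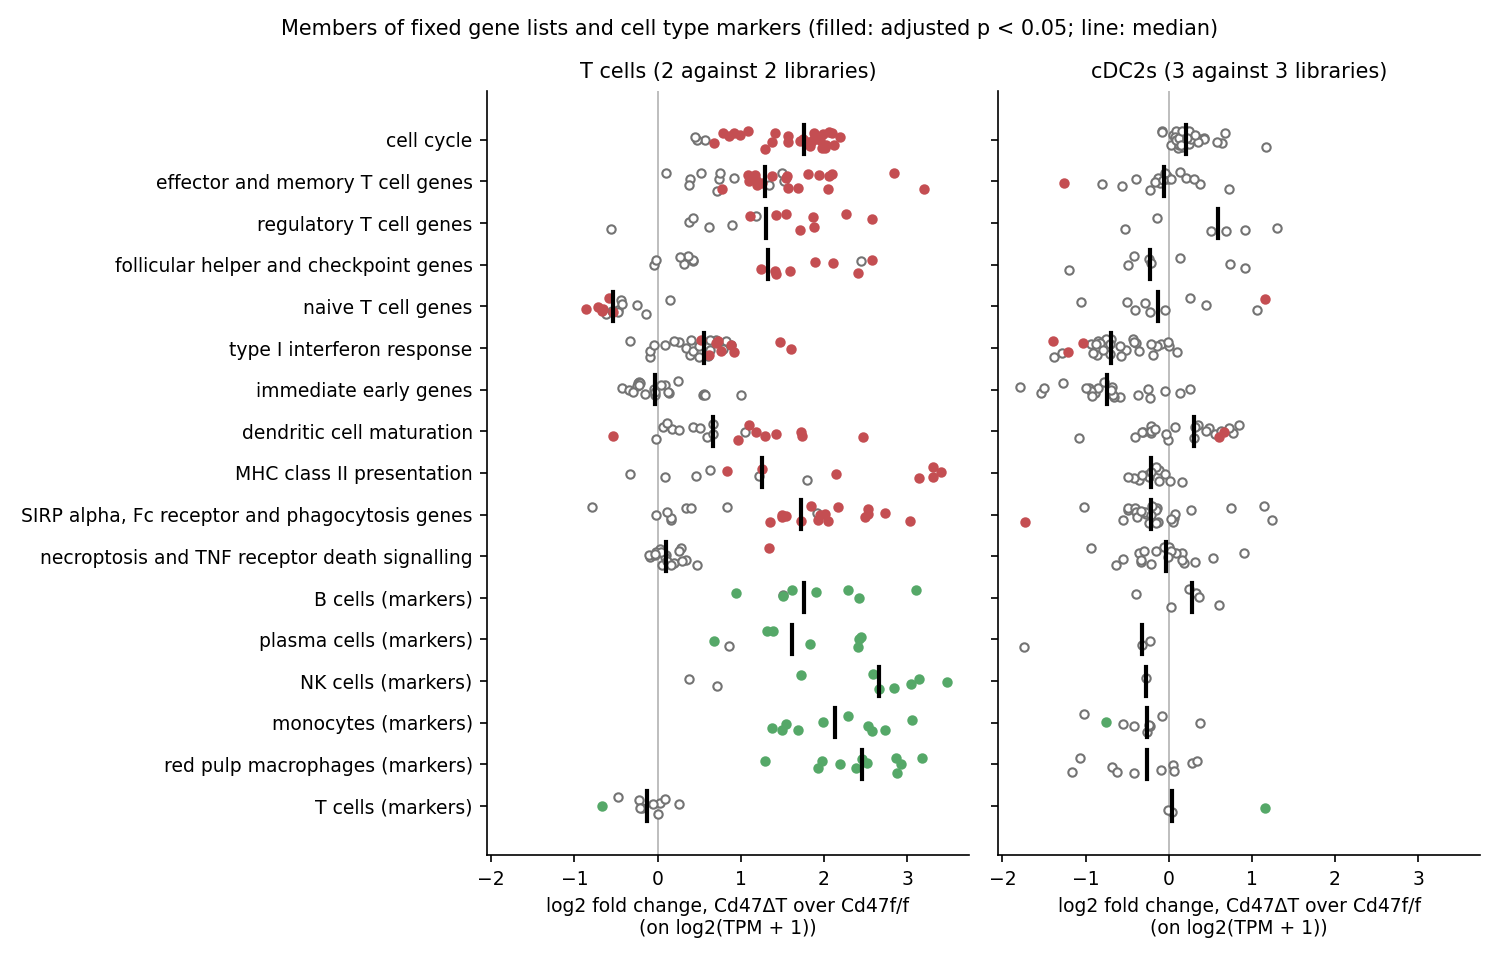
Log2 fold changes (Cd47ΔT over Cd47f/f, on log2(TPM + 1)) of the tested members of 11 gene lists and 6 marker lists in T cells (left) and cDC2s (right), with filled points past adjusted p under 0.05 (red, gene lists; green, markers) and black lines at the medians. The median of cell cycle genes is 1.76 in T cells and 0.21 in cDC2s, and that of type I interferon genes 0.56 and -0.70.

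Whether the genotype effect differed between the cell types was tested over 10650 genes with limma's interaction term. The log2 fold change was larger in T cells for 575 genes and smaller for 32. Type I interferon response genes were higher as a list in T cells and lower as a list in cDC2s, with a median difference of 1.18 on the log2 scale (adjusted p = 6.49e-16 by camera, and adjusted p = 0.0645 with an estimated correlation). Cell cycle genes were higher in both as lists, with a median difference of 1.35 on the log2 scale (adjusted p = 3.42e-21 by camera, and adjusted p = 0.0962 with an estimated correlation). Few genes were called in both cell types. Higher in both were 3, Samsn1, Car2 and Gm4956, where independent calls would give 1.30, and lower in both was 1, Cd4, where they would give 0.262. Higher in T cells and lower in cDC2s were 13, where independent calls would give 2.96: Anxa1, Ccl3, Cd209a, Cd81, Glrx, Ifit3, Ifitm6, Itgam, Kmo, Krt80, Plac8, Tgfbi and Tifab. Tcf7 was the 1 gene lower in T cells (log2 fold change -0.67) and higher in cDC2s (1.16), where independent calls would give 0.115. Those of these genes outside the naming rule were chosen after their values were seen. By a class also chosen after the data were seen, 39.3% of the genes higher in T cells were at least 4 times as high in control cDC2s as in control T cells, against 8.22% of all genes tested there. So were 10 of the 13 genes higher in T cells and lower in cDC2s, and 389 of the 575 with a larger log2 fold change in T cells (67.7%, against 9.59% of genes tested in both). The class and these calls use the same control libraries, so part of each excess is built in. Sex-linked transcripts differed between the cell types. Xist read 111 to 136 TPM in the cDC2 libraries, where Ddx3y was listed at 0, whereas every T cell library held Ddx3y, so that sex, kit and cell type cannot be told apart in this difference. Larger effects in T cells made up 94.7% of these calls, 80.2% under quantile scaling and 83.8% under median-of-ratios scaling. Larger and smaller effects numbered 307 and 76 under quantile scaling, 429 and 83 under median-of-ratios scaling and 375 and 20 with a filter of 5 TPM. They numbered 310 and 20 without T cell control library 1, 590 and 17 without T cell control library 2, and 366 and 14 or 291 and 11 without Cd47ΔT T cell library 1 or 2.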

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

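All tests of explanations in this part were chosen after the result was seen. In Cd47ΔT T cells, 96.6% of 29 tested markers of B cells, monocytes and red pulp macrophages passed as higher. A marker under 1 TPM in a control library was tested only where a Cd47ΔT library reached 1 TPM. The filter therefore favours markers that are higher. Their median log2 fold change of 2.29 was 2.19 under median-of-ratios and 1.85 under quantile scaling. The median of all genes moved from 0.10 to -0.0408 and -0.0812, so a shift shared by all genes was small beside this rise. With so small a shift the marker median could hardly have fallen far, so the outcome was largely set beforehand. A share of at least 80% past the threshold under both scalings was the test first written for TPM scaling. It came out at 82.8% and 72.4% and left TPM scaling undecided, and the median was then used instead. More RNA of other cells in the T cell preparations, from contaminating, attached or engulfing cells, may account for it, with Lyz2 at 194 and 349.7 TPM and Jchain at 309 and 345 TPM, and the labels name no gate that would remove such cells. Immunoglobulin segments, which B lineage cells transcribe, were higher in 99 of 175 tested, though the filter favours higher segments too. For these segments this argues against expression by T cells themselves. For the markers counted here, expression by T cells was not tested and stays open. Control T cell libraries held 3 of 8 B cell, 6 of 10 monocyte and 7 of 11 red pulp macrophage markers at 1 TPM or more. Of the tested markers, 0, 5 and 1 are also in a gene list. These control readings cannot decide it, since control libraries also held Jchain (57.0 and 64.3 TPM) and could hold RNA of other cells.

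Effector, regulatory, checkpoint and cell cycle lists were higher by camera (adjusted p = 0.515 each with an estimated correlation) in the same libraries, in which 10 of 11 tested marker lists of other cell types passed as higher. RNA from other cell types may account for the rise in part or in whole and cannot be told apart from a change in T cells, because both move with genotype over 2 libraries each, and a comparison of the rises between the 2 Cd47ΔT libraries was run and is not used, since it rests on single libraries. For control library 1, which holds both Xist and Y-linked transcripts, 4 of the 4 lists passed by camera without it. That fit leaves 1 control library and takes list members as nearly independent, so it cannot exclude control library 1 as a cause. A smaller share of naive T cells stays open and may account for part of the rise, as the naive list fell. Mean rises of 1.35 (effector, 30 genes), 1.17 (regulatory, 11) and 1.11 (checkpoint, 13) did not differ detectably (permutation p = 0.608). That permutation treats genes measured in the same libraries as independent, so the lack of a difference cannot decide it. A change per cell from loss of CD47 stays open, untested.

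Type I interferon and immediate early lists were lower by camera in Cd47ΔT cDC2s, and neither passed with an estimated correlation (adjusted p = 0.242 and 0.615). Small non-coding RNA in the TPM total would shift all genes alike. The median of all genes was -0.0729 as deposited, -0.0117 under protein-coding and 0.000833 under median-of-ratios scaling. Such a shared shift was small beside the fall of these lists. The bounds set for this explanation after the values were known could therefore hardly be missed. These bounds replaced a test by camera, which compares list members with other genes. The medians of -0.70 and -0.74 were no nearer 0 than -0.62 and -0.66 under protein-coding and median-of-ratios scaling. Upper quartiles of members were no higher than -0.29 and -0.34 there. For a single library, both lists stayed lower without each of the 6 libraries in turn (highest adjusted p by camera 2.81e-09 and 0.000598). These p-values take list members as nearly independent, while the estimated correlations were 0.15 and 0.69. Passing therefore cannot exclude a single library, and only the kept direction is shown. A changed mix of cDC2 subsets cannot be told apart from a change per cell, because each library gives 1 value per gene for all its cells. Of 14 fixed cDC2 markers, 3 were lower, neither none nor most. That count cannot decide it, since the marker list does not separate cDC2 subsets. A difference in library quality was not tested and stays open. The small RNA share can be a sign of such a difference, which would move with genotype. An effect of the T cells of Cd47ΔT mice on cDC2s also stays open, as a hypothesis.

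The genotype effect differed between T cells and cDC2s, by camera or limma on the interaction term, for 13 of 25 lists and 64 of 115 named genes tested in both. With an estimated correlation no list differed (smallest adjusted p = 0.0645 by camera). Median differences of log2 fold changes, T cells minus cDC2s, were 0.62 (apoptosis BCL2 family and caspases), 0.64 (immediate early genes), 1.18 (type I interferon response), 0.34 (interferon gamma response), -0.37 (naive T cell genes), 1.54 (effector and memory T cell genes), 0.89 (follicular helper and checkpoint genes), 1.35 (cell cycle), 1.33 (MHC class II presentation), 1.91 (SIRP alpha, Fc receptor and phagocytosis genes), 0.87 (cytokines and TNF superfamily ligands), 2.12 (chemokines) and 0.0391 (cytosolic ribosomal proteins). For ribosomal proteins the median difference was positive while the test called the list smaller in T cells. Among named genes higher in T cells and not past the threshold in cDC2s, the differences of log2 fold changes were Tyrobp (3.42), Cd74 (3.57), H2-Ab1 (3.63), Fcgr4 (3.55), H2-Aa (3.47), Il1r2 (3.94), H2-Eb1 (3.39), Entpd1 (2.59), S100a4 (1.89), Sirpa (3.12), Fcer1g (3.24), Oas1a (2.03), Ebi3 (2.82), Ccl6 (3.15), Tk1 (1.71), Birc5 (1.72), Cd44 (1.60), Cd83 (1.92), Rrm2 (1.59), Isg20 (1.74), Kif11 (1.62), Tnfsf14 (2.92), Cdk1 (1.94), Itgax (2.01), C1qb (2.84), Mx1 (2.17), Ccl5 (1.27), Cxcl10 (2.20), Cd40 (1.73), Lgals1 (1.5), Bcl2a1b (0.75), Bcl2a1d (1.17), Ccnb1 (1.07), Cox5b (0.67), Xbp1 (0.90) and Mertk (1.88). Genes that passed as higher in T cells and lower in cDC2s, by these differences, were Cd209a (3.85), Itgam (3.22), Ccl3 (3.08) and Ifit3 (1.82). Genes with a larger log2 fold change in T cells that did not pass there as higher had differences of Dusp6 (2.48), Bank1 (3.27), Oasl2 (2.02), Irf7 (1.42), Cd101 (1.78), H2-DMa (0.89), H2-Oa (0.99), Gbp4 (1.27), Ifi213 (1.30), Emb (1.18), Il1b (3.51), Ifit1bl1 (1.20) and Zbp1 (1.28). Among genes with a smaller log2 fold change in T cells, those past the threshold there were St8sia6 (-2.88), Tcf7 (-1.84), Cd47 (-1.94), Il7r (-1.78), Actn1 (-1.12) and Ccr7 (-0.99), and the others were Mdk (-1.93), Nab2 (-1.65), Ltb (-0.64), Lad1 (-1.52) and Timm22 (-1.56).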

How the results depend on the processing

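Protein-coding scaling was chosen after the data were seen, and all other alternatives before. The fall of Cd47 in T cells kept its direction and passed under every alternative except no filter (-1.95, adjusted p = 0.0872 by limma), and no named gene past the threshold turned direction under any alternative. With no filter, limma called 14 higher and 1 lower in T cells and 2 higher and 4 lower in cDC2s, over 20437 and 18337 genes. Of named calls, 4 of 69 and 2 of 31 stayed, and the T cell receptor list in cDC2s had adjusted p = 0.790 in the other direction. With a filter of 5 TPM, 679 genes were higher in T cells, and the interaction test called 375 effects larger and 20 smaller there. In cDC2s the checkpoint (0.805) and heat shock (0.652) lists turned direction without passing. Under quantile scaling T cells had 655 higher and 336 lower genes and 1 lower list, and the interaction test called 307 effects larger and 76 smaller. Ripk1 (-0.0875), Casp8 (-0.0804) and Cd47 in cDC2s (0.0666) turned sign without passing. Under median-of-ratios scaling 264 genes were lower in T cells, 83 effects were smaller there and 2 lists were lower in cDC2s. Ripk1 (-0.10), Casp8 (-0.12), Cd47 in cDC2s (0.0781) and the lists of necroptosis in T cells (adjusted p = 0.906) and MHC class I (0.950) and heat shock (0.786) in cDC2s turned direction without passing. Under protein-coding scaling Casp8 (-0.00566), Cd47 in cDC2s (0.0646) and heat shock in cDC2s (adjusted p = 0.890) did so. Without the variance trend cDC2s had 7 higher and 5 lower genes, and in 1 fit of all libraries 68 higher and 103 lower and 3 lower lists. With an estimated correlation 0 lists were higher and 0 lower in T cells, and 0 and 0 in cDC2s. Replicate numbers were not taken to pair the libraries, though pairing cannot be excluded. Deviations of same-numbered libraries correlated across genes at 0.190 in T cells and at -0.0438, 0.0591 and 0.119 in cDC2s. There control library 1 did not correlate best with its own number, while control libraries 2 and 3 did. Among Cd47ΔT cDC2 libraries only library 3 did, and library 2 correlated best with control library 1 (0.119). In T cells Xist was read mainly in library 1 of each genotype (33.2 and 6.21 TPM, against 0 and 0.01), which would go with pairing. With the number as a replicate block T cells had 1986 higher and 310 lower genes and cDC2s 3 higher and 1 lower. Of the cDC2 calls, 3 of the 76 and 1 of the 31 named ones stayed past the threshold. In T cells the block leaves almost no spread within a gene, so its counts and passes there carry little weight. Ripk3 (0.0465), Bcl2 (0.00253) and Rpl8 (0.000977) in T cells and Egr1 in cDC2s (0.0497) passed by limma with the block. There the necroptosis list in T cells had adjusted p = 0.815 in the other direction. Lists no longer past the threshold were those of apoptosis (0.0506), immediate early (0.146) and unfolded protein response genes (0.254) in T cells and interferon gamma (0.0523) in cDC2s. With each library left out in turn, T cells had 585 to 1439 higher and 51 to 140 lower genes, cDC2s 0 to 9 and 0 to 5 genes and 2 to 5 higher and 2 to 5 lower lists. Effects by the interaction test were larger in T cells for 291 to 590 genes and smaller for 11 to 39. Log2 fold changes that turned sign this way ranged from -0.0287 to 0.0915 (Casp8), -0.19 to 0.29 (Ripk1) and -0.16 to 0.13 (Tnfrsf1a) in T cells, and -0.0540 to 0.0621 (Cd47), -0.0902 to 0.25 (Cd80), -0.31 to 0.49 (Fasl) and -0.15 to 0.22 (Mertk) in cDC2s. Adjusted p of lists that turned direction ranged from 0.234 to 0.992 (necroptosis), 0.0314 to 0.884 (interferon gamma), 0.0768 to 0.945 (MHC class I), 5.89e-39 to 0.872 (ribosomal) and 0.000593 to 0.380 (heat shock) in T cells, and 0.313 to 0.953 (chemokines), 0.474 to 0.953 (cholesterol), 0.428 to 0.953 (effector) and 0.537 to 0.894 (heat shock) in cDC2s. Where no cause is named, the cause was not tested. Of the 10 splits of the 6 cDC2 libraries into 3 against 3, 1, the real split, gave 76 genes and 9 lists and the highest other 4 and 5, and so few splits cannot give a share under 0.05. Depth is unknown, so its limits could not be computed.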

Other observations

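The tests, groups and genes in this part were chosen after the data were seen. Genes encoded in the mitochondrial genome were lower in Cd47ΔT T cells, 11 of 15 past the threshold with a median log2 fold change of -0.54, while nuclear genes of oxidative phosphorylation were higher as a list (adjusted p = 6.43e-07 by camera, and adjusted p = 0.633 with an estimated correlation). The median of the former was -0.69 under median-of-ratios scaling (3 past the threshold) and -0.51 under quantile scaling (9 past), and 5 to 10 passed with 1 T cell library left out. Immunoglobulin segments, which B lineage cells transcribe, made up 99 of the 1058 higher genes, out of 175 tested. Another 416 were at least 4 times as high in control cDC2s as in control T cells, 39.3% of the higher genes against 8.22% of all tested, and 543 were in neither class. The levels of the 2 cell types come from different kits. The class and the calls use the same control T cell libraries, so part of this excess is built in.

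Ly6c1 fell while its near-identical neighbour Ly6c2, a monocyte and memory T cell gene, rose from 667 ± 101 to 1722 ± 22.3 TPM in T cells (log2 fold change 1.38 ± 0.12, adjusted p = 0.00440 by limma), and reads can be split wrongly between such copies. Gm15518 is annotated as an antisense gene (chromosome 16, 49758576 to 49798870, minus strand, GRCm38). By strand, 1662 bases lie between its start and that of Cd47, and the 2 do not overlap. It read 1.73 and 0.210 TPM in control and 7.76 and 7.79 TPM in Cd47ΔT T cells (log2 fold change 2.27 ± 0.39, adjusted p = 0.0212 by limma, and 0.0670 under quantile scaling). Of 19 genes within 5 Mb of Cd47, 4 passed in T cells, against 1162 of 12434 others (two-sided Fisher's exact p = 0.0954). The 4 include Trat1 and Gm15518, the latter singled out above for its change, so the count is not independent of that choice. In cDC2s 0 of 14 passed, against 76 of 12044 others (p = 1 by the same exact test).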
